A study of Homo sapiens with 67 samples.

How the data were processed

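Polyadenylated RNA was isolated with Trizol from 67 fresh-frozen, untreated oesophageal adenocarcinoma tissues, and libraries were made with a standard Illumina procedure, per the labels' protocols. Reads were placed on genome build hg38, per the submitters' processing notes; the aligner, the counting tool and the annotation release are not given in the sources used here. The deposited table holds 45413 genes by 67 samples, 1 column per tissue, with values read here as TPM. The file does not name its unit. TPM was inferred from the values: each column sums to between 999625 and 1000150, values carry 3 significant digits, and in no library are over 11.4% of the low values whole multiples of its lowest value (tolerance 0.02), whereas CPM of whole reads would be such multiples. TPM keeps no depth, so the depth per sample is unknown and no interval or floor that needs counts was computed.

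Of the rows of deposited TPM values, 25830 are 0 in every sample, among them 20125 of 20167 non-coding RNAs and 398 of 408 immunoglobulin and T-cell receptor genes, against 455 of 19521 protein coding genes in GENCODE 29. The values therefore cover protein coding genes almost alone, and a 0 for a non-coding gene is no measurement of absence. Because TPM values of a library share a fixed sum, a few very abundant genes lower all others. Y-linked genes and XIST were left out of every step.

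Values were analysed as log2(TPM + 1). Genes at 1 TPM or more in at least 7 samples were kept (16515 genes). Each gene was regressed on the log2(TPM + 1) of 7 anchor genes (CDX2, MUC5AC, TP63, CD8A, COL1A1, MKI67 and ERBB2) with limma 3.58.1 in R 4.3.3, with a trend and robust empirical Bayes moderation, and p-values were adjusted by the Benjamini-Hochberg method over 16514 genes at a threshold of 0.05. A fold change on this scale understates the change of low genes. The 33 gene lists, with 462 genes of which 438 passed the filter, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Of 86 combinations of list and anchor past the preset test, 10 held with an estimated correlation: intestinal epithelium with CDX2, gastric mucous epithelium with MUC5AC, squamous epithelium with TP63, cytotoxic cells and checkpoint genes with CD8A, fibroblast genes and transition factors with COL1A1, and proliferation, gastric gland and liver genes with MKI67.

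A list score is the mean of gene-wise z values over samples, with genes shared by both lists of a pair left out. Of 26 list pairs and 46 driver-neighbour pairs fixed in advance, correlations were computed with Pearson's r and Spearman's rho, each with 100000 permutations, in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. The smallest permutation p is 1e-05. A measure was taken to fall into separate parts where a mixture of 2 normal distributions (scikit-learn 1.9.0) improved the Bayesian information criterion by over 10 with Ashman's D over 2; correlations were then computed within parts of at least 6 samples. This rule was set after seeing the data. The neighbours of 2 pairs, both at 0 or not matched in the table, were not used here. Intervals are 95% Fisher intervals. A library counted as far above the median of a driver when it exceeded the median plus 3 × 1.4826 median absolute deviations. Gene coordinates are from GENCODE 29 on hg38, with 16166 of 16515 genes matched by symbol.

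Labels give no batch. Genes detected, mitochondrial share and dominance of single genes were listed per library, but no test for a batch was run, so one cannot be excluded. The most similar libraries correlated at r = 0.971 across genes with 805 genes differing over 2-fold, so no library was counted as a repeat. The sample titles number the tissues and name no patients, so 1 tissue per patient is an assumption. P-values measure the spread between tissues. The regression was tested on simulated data with 50 genes changed at each slope among 16514. At a slope of 0.5, 94% were recovered for CDX2, 100% for MUC5AC, 96% for TP63, 78% for CD8A, 98% for COL1A1, 86% for MKI67 and 94% for ERBB2. False calls were between 3.16% (CD8A) and 8.15% (ERBB2). Each gene was shuffled on its own there, which removes the correlation between genes, so these rates do not cover correlated genes. With that correlation kept, the highest count over 100 permutations of the ERBB2 values was 3834 genes.

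Named genes followed a rule set before the data were examined: members of the fixed lists and pairs, the 10 largest positive and 5 largest negative moderated statistics per anchor, the 20 genes with the largest SD and the 10 with the highest mean, leaving out antigen receptor segments and unnamed loci from the statistics and the SD. Some genes under this rule are not reported here. Also set in advance were alternatives of a pseudocount of 0.1, no filter, rank correlation, leaving out the 2 samples farthest from the median, a plain mean in place of z values for scores, 5 median absolute deviations in place of 3, scores of glandular, fibroblast and cytotoxic content as covariates (the score of the anchor's own cell type left out) and quantile normalization. Alternatives added after seeing the data were fits without the 3 libraries with a gene above 100000 TPM, with the squamous score or the mitochondrial share as a covariate, and within separate parts.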

Results

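RNA was measured in 67 fresh-frozen oesophageal tissues from patients with oesophageal adenocarcinoma, a gland-forming cancer of the lower oesophagus, none of whom had been treated. All 67 libraries belong to 1 group, with no normal tissue, treatment or other contrast in the labels. The values therefore describe levels, the spread between tissues and associations over tissues. The values were read as TPM, which scales each library to a sum of 1000000 and keeps no record of depth, so the depth is unknown and no interval that needs counts is given. A library held between 15941 and 17669 genes above 0 TPM (mean 16891 ± 321, SD, n = 67), and between 13099 and 15479 genes at 1 TPM or more. Mitochondrial transcripts took 9.62% ± 3.79 of the TPM (SD, n = 67), with a range of 3.97% to 19.9%. The 20 highest genes of a library took a median of 18.8% of its TPM, with a range of 12.2% to 66.8%. In 3 libraries at least 1 gene exceeded 100000 TPM; the highest genes there were PGA3, LIPF and GKN1, secreted products of the gastric mucosa.

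The first question was which cell types and programmes the tissues expressed. Glandular epithelial genes were high in nearly all libraries: KRT8, a keratin of simple epithelia, had a median of 770 TPM (range 12.4 to 2620), and EPCAM, an epithelial adhesion molecule, had a median of 404 TPM (8.81 to 1570). Squamous epithelial genes were also abundant in the median library and more variable. KRT13, a keratin of the upper layers of squamous mucosa, had a median of 3160 TPM with a range of 21.7 to 52400, and KRT5, a basal keratin, had a median of 1120 TPM with a range of 5.03 to 9610. The 20 squamous genes had a median SD of 3.4 on the log2(TPM + 1) scale, against 0.60 for all genes past the filter.

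Squamous genes divided the libraries into separate parts. A mixture of 2 normal distributions placed 45 libraries at 164 TPM of KRT5 or more and 22 at 47.6 TPM or less. TP63, the transcription factor of squamous basal cells, was at 3.63 TPM or more in 43 libraries and at 1.68 TPM or less in 24. The score of the whole squamous list, the mean of its gene-wise z values, placed 41 libraries in the higher part and 26 in the lower. No such division was found for CDX2, MUC5AC, CD8A, COL1A1 or MKI67. The parts were defined from the data and are not groups of the study.

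Intestinal and gastric genes were present at widely spread levels. CDX2, an intestinal transcription factor, had a median of 8.72 TPM (0 to 42), and its target CDH17, an intestinal cadherin, had a median of 129 TPM (1.37 to 684). The gastric mucin MUC5AC had a median of 131 TPM (0.639 to 5870), the mucosal peptide TFF1 a median of 1150 TPM (5.67 to 37800), and the gastric tight junction gene CLDN18 a median of 375 TPM (1.72 to 3680). Gastric gland genes differed in level: the 10 chief and parietal cell genes had a median of 0.368 TPM over their medians, but the medians of PGC (40.9 TPM), LIPF (22 TPM), PGA3 (4.03 TPM) and GHRL (2.89 TPM) were higher, and their score placed 3 libraries apart from the other 64.

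**Figure D1:**
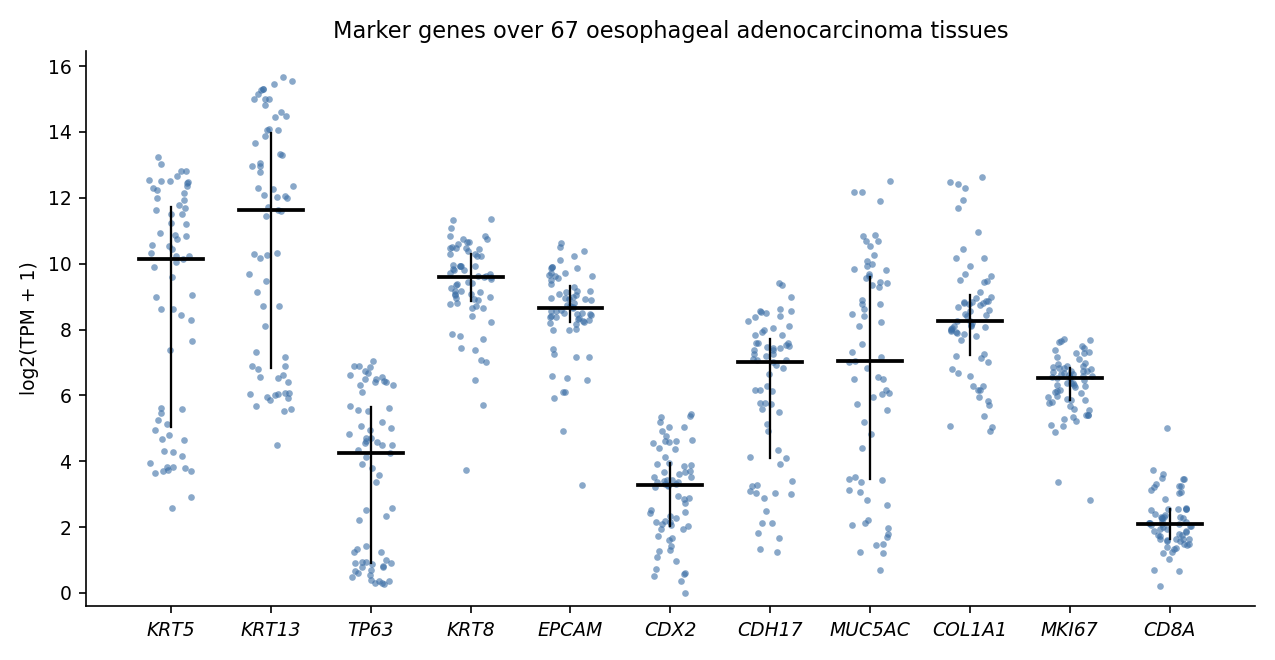
Levels of 11 marker genes in 67 libraries, each point being 1 library, on the log2(TPM + 1) scale; horizontal bars are medians and vertical bars the quartiles. KRT5, KRT13 and TP63 fall into separate lower and higher parts; the median of KRT8 is 770 TPM and that of EPCAM 404 TPM.

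Stromal and immune genes were detected throughout. The matrix collagen COL1A1 had a median of 308 TPM (29.2 to 6350), the endothelial gene VWF 76.8 TPM (21.5 to 237) and the macrophage complement gene C1QA 98.4 TPM (14.8 to 430). CD8A, the co-receptor of cytotoxic T cells, was low, with a median of 3.27 TPM (0.168 to 31.5), and the checkpoint ligand CD274 had a median of 7.42 TPM (1.3 to 83). The calcium-binding alarmin S100A9, which neutrophils and squamous epithelium both express, had a median of 7670 TPM (56.4 to 71500). MKI67, a marker of cycling cells, had a median of 91.4 TPM (6.03 to 210). Among antibody and drug targets, CEACAM5 had a median of 1020 TPM, ERBB2 of 114 TPM and VEGFA of 124 TPM. All 13 tumour suppressor genes of the fixed list passed the filter, with a median of 27.7 TPM over their medians; FHIT was at 1.65 TPM and CDKN2B at 39.3 TPM.

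The second question was which genes varied with 7 anchor genes chosen for cell identity, immune content, stroma, growth and a therapeutic target. Slopes are log2 changes per doubling of the anchor's TPM + 1, fitted with limma over 67 libraries with Benjamini-Hochberg adjustment over 16514 genes. With CDX2, intestinal genes rose together: 22 of 24 members of the intestinal list rose and none fell (23 adjusted over the list alone), with a median slope of 0.81. CDH17 rose by 1.2 ± 0.13 (SE; adjusted p = 1.77e-09) and CDX1, a sister transcription factor, by 1.14 ± 0.14 (adjusted p = 1.43e-08). GUCY2C, the intestinal guanylate cyclase receptor (chromosome 12, 14612632 to 14696585, hg38), rose by 1.13 ± 0.11 (adjusted p = 2.04e-11), and HEPH, an iron oxidase of enterocytes, by 0.80 ± 0.076 (adjusted p = 9.92e-12). OLFM4, a crypt stem cell gene, rose by 1.2 ± 0.24, whereas KRT20 did not pass the test (slope 0.49 ± 0.24, adjusted p = 0.0997) except without the 3 libraries with a gene above 100000 TPM (0.67, adjusted p = 0.0423).

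Other genes that led the association with CDX2 were AGMAT, CLRN3, DDC, MOGAT3, NR5A2 and AOC1, with slopes from 0.54 to 0.97. The strongest negative slopes were small: EPHB6 fell with a slope of -0.40 ± 0.083 and TSPAN5 with -0.35 ± 0.073. The intestinal list was the only one of 33 to pass camera with an estimated correlation in the main fit (adjusted p = 0.000871). Of 17 general glandular genes, 11 rose (12 adjusted over the list alone; adjusted p = 0.637 with an estimated correlation, and 0.0194 after quantile normalization, where 7 rose), among them EPCAM at 0.58 ± 0.090. The 20 squamous genes held no call in either direction, with a median slope of -0.28 (adjusted p = 8.29e-09 with the preset correlation and 0.637 with an estimated correlation); KRT13 had a slope of -0.34 ± 0.30. In all, 4665 genes rose and 245 fell with CDX2, but after quantile normalization 685 rose and 579 fell. With scores of glandular, fibroblast and cytotoxic content as covariates, 401 genes were called, and 13 of the 24 intestinal genes rose.

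With MUC5AC, the gastric mucous programme rose: 13 of 14 list members rose and none fell (13 adjusted over the list alone), with a median slope of 0.58 and adjusted p = 2.64e-06 with an estimated correlation. TFF2, a peptide of mucous neck cells (chromosome 21, 42346357 to 42351128), rose by 0.92 ± 0.064 (adjusted p = 3.39e-18), and TFF1 by 0.76 ± 0.059 (adjusted p = 4.84e-16). VSIG1, MUC6, CLDN18 and CTSE rose with slopes of 0.70, 0.71, 0.62 and 0.59. Outside the list, the bicarbonate transporter SLC4A4 (0.42 ± 0.039), CAPN8 (0.39 ± 0.040) and MUCL3 (0.66 ± 0.067) were among the strongest. Glycolysis and hypoxia genes went the other way: 10 of 17 fell and 1, the carbonic anhydrase CA9 (slope 0.30), rose (10 and 1 adjusted over the list alone; adjusted p = 0.0674 with an estimated correlation).

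SLC2A1, the glucose transporter, fell by 0.17 on the log2 scale per doubling of MUC5AC (SE 0.033), and the glycolytic enzyme ENO1 fell by 0.087. HILPDA, a hypoxia-inducible lipid droplet gene, had the most negative statistic (slope -0.21 ± 0.035, adjusted p = 4.97e-06). Of the B and plasma cell genes, 10 of 14 rose (13 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), including JCHAIN at 0.34 ± 0.072. All 7 mast cell genes rose (7 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation). In all 2205 genes rose and 786 fell; after quantile normalization 1819 rose and 1625 fell. Without the 3 libraries with a gene above 100000 TPM, 2810 rose and 458 fell.

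With TP63, the squamous programme moved as a block: all 19 other squamous genes rose (19 adjusted over the list alone), with a median slope of 1.36 and adjusted p = 1.69e-11 with an estimated correlation. CERS3, a ceramide synthase of barrier lipids, rose by 0.99 ± 0.016 (adjusted p = 2.12e-57), the desmosomal cadherin DSC3 by 1.17 ± 0.022, and the crosslinking enzyme TGM1 by 1.26 ± 0.030. KRT5, KRT13 and CRNN had slopes of 1.37, 1.42 and 1.43. Because TP63 fell into separate parts, the fit was repeated within each. Among the 43 libraries of the higher part, all 19 squamous genes again rose, with a median slope of 1.11, and 1331 genes rose and 9347 fell in all.

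Within that higher part 56.6% of all genes fell, with a median slope of -0.14, and many members of other lists fell with them. Of 25 intestinal genes 17 fell and none rose, of 15 gastric mucous genes 12 fell and 1 rose, and of 20 proliferation genes 18 fell and none rose. CDH17 had a slope of -0.60 ± 0.20 (adjusted p = 0.0104), MUC5AC of -1.37 ± 0.31 (adjusted p = 0.000268), and MKI67 of -0.28 ± 0.066 (adjusted p = 0.00045). Fibroblast genes fell in 18 of 21 cases (the counts of these 4 lists were the same adjusted over the list alone), and COL1A1 had a slope of -0.51 ± 0.15. None of these 4 lists passed camera there (adjusted p from 0.14 to 0.904, and 0.977 with an estimated correlation), nor over all libraries (0.943 with an estimated correlation), whereas the squamous list did within the part (4.81e-06). Other lists had fewer falls than all genes: 6 of 17 general glandular genes fell and 1 rose, with a median slope of -0.10 (6 and 1 adjusted over the list alone), none of 17 cytotoxic genes was called (median slope 0.019), and 23 interferon genes had a median slope of 0.051, each list at adjusted p = 0.977 with an estimated correlation. Among the 24 libraries of the lower part 1 gene passed the limma test, CLCA4 (slope 2.11, adjusted p = 0.0248), named here after its value was seen. There 410 of 16514 genes had an unadjusted p under 0.05, below the share of 0.05 expected with no association. Over all 67 libraries 1525 genes rose and 8865 fell with TP63; after quantile normalization 2615 rose and 4140 fell.

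With CD8A, cytotoxic lymphocyte genes rose: 15 of 16 list members rose and none fell (16 adjusted over the list alone), with a median slope of 0.64 and adjusted p = 2.91e-11 with an estimated correlation. The chemokine CCL5 rose by 0.94 ± 0.089 (adjusted p = 7.53e-12), the granzyme GZMK by 0.86 ± 0.095 (adjusted p = 9.25e-10) and perforin, PRF1, by 0.79 ± 0.095. T-cell genes outside the list, such as GPR174, THEMIS, GPR171, CD96 and KLRK1, had slopes from 0.58 to 0.77. Of 14 checkpoint and regulatory T-cell genes 4 rose, PDCD1, TIGIT, LAG3 and IDO1 (9 adjusted over the list alone), and the list kept adjusted p = 0.0101 with an estimated correlation; TIGIT rose by 0.48 ± 0.084 and CD274 did not pass (0.33 ± 0.14, adjusted p = 0.651).

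Interferon genes rose in 4 of 23 cases with CD8A (9 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation), which were GBP4, GBP5, IRF1 and the chemokine CXCL9 at 1.09 ± 0.21. Antigen presentation genes held no call over all genes, although 10 of 13 class I and 8 of 10 class II members passed when adjusted over the list alone (both lists at adjusted p = 0.133 with an estimated correlation). In all 164 genes rose and none fell. In the limma fit 961 of 16514 genes had an unadjusted p under 0.05, little above the share of 0.05 expected with no association. The Spearman test called 136 genes higher and 1 lower, ANXA2, named here after its value was seen.

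With COL1A1, extracellular matrix genes rose most steeply. The median slope of all genes was 0.11 here and 0.0023 after quantile normalization, so slopes are given relative to the median of all genes. All 20 other fibroblast and matrix genes rose (20 adjusted over the list alone; adjusted p = 0.000327 with an estimated correlation), with COL1A2 at 0.76, COL5A1 at 0.65, COL3A1 at 0.75 and the fibroblast protease FAP at 0.79 above the median. ADAMTS2, a procollagen protease, stood at 0.68 and SPARC at 0.64. All 12 transition factors rose (12 adjusted over the list alone; adjusted p = 0.00917 with an estimated correlation), including ZEB1 at 0.34 and TWIST1 at 0.35. The 20 and the 12 genes were also all called higher after quantile normalization.

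Macrophage genes rose in 14 of 15 cases with COL1A1 (14 adjusted over the list alone; adjusted p = 0.391 with an estimated correlation), with SPP1 at 0.88 and CD163 at 0.37 above the median of all genes; 10 of 15 were higher after quantile normalization. All 14 endothelial genes rose (14 adjusted over the list alone; adjusted p = 0.343 with an estimated correlation), and 13 did after quantile normalization. Of 14 neutrophil and acute inflammation genes 10 rose and 2, S100A8 and S100A9, fell (10 and 2 adjusted over the list alone; adjusted p = 0.795 with an estimated correlation), with a list median of 0.49 above that of all genes. Squamous genes fell in 19 of 20 cases under either scaling (19 adjusted over the list alone; adjusted p = 0.161 with an estimated correlation), and the slope of KRT13 relative to the median of all genes was -0.98. In all 10515 genes rose and 932 fell, against 3454 and 3065 after quantile normalization, where 205 calls had the opposite direction.

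With MKI67, cell cycle genes rose: all 19 other proliferation genes rose (19 adjusted over the list alone), with adjusted p = 0.00565 with an estimated correlation. The median slope of all genes was 0.22, and 0.015 after quantile normalization, so slopes are again relative to that median. The mitotic kinesin KIF11 stood at 0.54 (slope 0.76 before subtraction, with adjusted p = 1.38e-27 for a difference from 0), the spindle factor TPX2 at 0.76, the centromere protein CENPF at 0.68 and TOP2A, a topoisomerase of dividing cells, at 0.88. All 19 were also higher after quantile normalization. The strongest negative statistics belonged, in order, to the epithelial sodium channel subunits SCNN1G (-1.49) and SCNN1B (-1.82), ATP13A5 (-0.79), RPS6KA6 (-0.67) and the alcohol dehydrogenase ADH7 (-2.14), with slopes relative to the median in parentheses.

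Gastric gland genes fell in 8 of 9 cases with MKI67 under either scaling (8 adjusted over the list alone; adjusted p = 0.0463 with an estimated correlation, and 0.627 after quantile normalization), among them PGA3 and the proton pump gene ATP4A. The score of this list placed 3 libraries apart from the other 64, and the list count was not repeated without them. Squamous genes fell in 15 of 20 cases (17 adjusted over the list alone; adjusted p = 0.197 with an estimated correlation), but in 2 of 20 after quantile normalization. Of 10 liver genes 5 fell, TF, ALB, FGG, CYP2E1 and TTR, and 1, the protease inhibitor SERPINA1, rose (5 and 1 adjusted over the list alone; adjusted p = 0.00565 with an estimated correlation, and 0.602 after quantile normalization). Most liver genes were near 0: only 2 of the 11 on the list had a median of 1 TPM or more, with a median of 0.182 TPM over their medians. All 21 fibroblast genes rose (21 adjusted over the list alone; adjusted p = 0.777 with an estimated correlation), and 13 did after quantile normalization. Neutrophil and acute inflammation genes had the largest list median, 0.72 above that of all genes: 10 of 14 rose and none fell (10 and 1 adjusted over the list alone; adjusted p = 0.915 with an estimated correlation), and 3 rose after quantile normalization. In all 10285 genes rose and 728 fell, against 1958 and 1712 after quantile normalization, where 59 calls had the opposite direction; with composition scores as covariates 2489 genes were called.

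With ERBB2, the receptor also named HER2, 46 genes rose and 7 fell, and the leading genes lay beside it on chromosome 17. Of the 46 genes, 34 were on chromosome 17, which holds 6.07% of the genes tested; 16 lay within 0.5 Mb of ERBB2 and 25 within 2 Mb. MIEN1 (39728496 to 39730787, hg38) rose by 0.96 ± 0.059 (adjusted p = 3.96e-21), GRB7 (39737927 to 39747291) by 0.78 ± 0.063 (adjusted p = 2.66e-15), and PGAP3 (39671122 to 39696797) by 0.68 ± 0.062 (adjusted p = 6.92e-13). MED24, ORMDL3, STARD3, PSMD3 and TCAP, also within 0.5 Mb, had slopes from 0.56 to 0.64. Among genes that fell, SNRPN had a slope of -0.26 ± 0.057 (adjusted p = 0.0136), which did not pass after quantile normalization (adjusted p = 0.154).

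ERBB2 itself fell into separate parts, with 4 libraries at 961 TPM or more and 63 at 373 TPM or less. Within the 63 libraries 10 genes passed, 3 of them shared with the fit over all libraries: MIEN1 (slope 0.67 ± 0.10), GRB7 (0.72 ± 0.11) and PGAP3 (0.67 ± 0.091). MED24, ORMDL3, STARD3, PSMD3 and TCAP did not pass there (adjusted p from 0.169 to 0.293). In the permutation test of driver-neighbour pairs, adjusted over fewer relations, STARD3 passed by r in these 63 libraries (0.395, adjusted p = 0.00174). It did not pass by rho (0.191, adjusted p = 0.151). The annotated spans of MIEN1 and PGAP3 overlap that of ERBB2, so their values are uncertain where the counting did not separate the reads. No fixed list passed camera with an estimated correlation for ERBB2 (lowest adjusted p = 0.0986, adipocytes). The 20 squamous genes held no call in either direction (median slope -0.67; adjusted p = 0.563 with an estimated correlation).

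**Figure D2:**
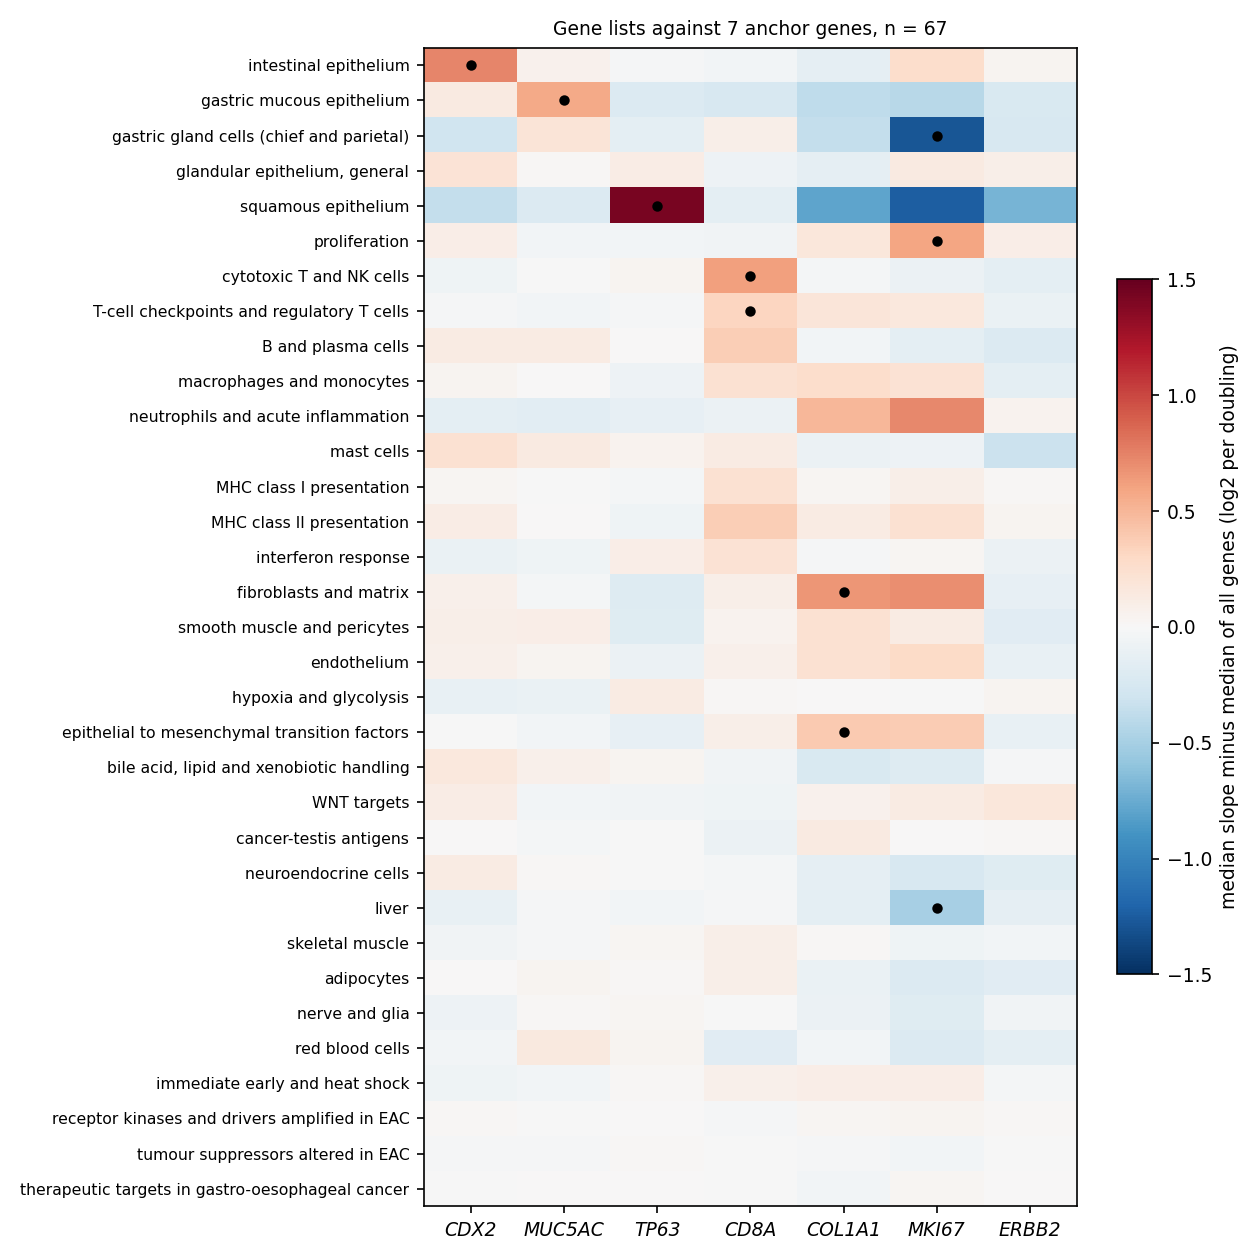
Median slope of each of 33 gene lists (rows) on 7 anchor genes (columns) over 67 libraries, minus the median slope of all genes, in log2 per doubling of the anchor's TPM + 1; red is higher and blue lower. Black dots mark the 10 combinations with camera adjusted p under 0.05 with an estimated correlation, such as squamous epithelium with TP63 (adjusted p = 1.69e-11).

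The third question was how the cell type and programme scores varied together. Of 29 relations, 20 passed at an adjusted p under 0.05 (permutation tests, two-sided, Benjamini-Hochberg over the 29 relations). The stroma moved as a unit. The fibroblast score correlated with endothelium at r = 0.809 (rho = 0.829), with macrophages at r = 0.817 (rho = 0.803) and with smooth muscle and pericytes at r = 0.76 (rho = 0.731), each with permutation p = 1e-05, the smallest the permutations can give, and adjusted p = 2.42e-05. Without the 2 libraries farthest from the median these were 0.804, 0.811 and 0.72. The fibroblast and transition factor scores correlated at r = 0.965 (rho = 0.942).

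Cytotoxic cells rose with other immune programmes. Their score correlated with checkpoint and regulatory T-cell genes at r = 0.761 (rho = 0.745; 0.719 without the 2 farthest libraries), with MHC class II at r = 0.63 (rho = 0.641; 0.578) and with MHC class I at r = 0.574 (rho = 0.566; 0.523), each with permutation p = 1e-05. With macrophages r was 0.558 (rho = 0.568), and 0.316 after quantile normalization (adjusted p = 0.0165), and with the interferon response 0.45 (rho = 0.454, permutation p = 0.00015, adjusted p = 0.000335). The relation to fibroblasts (r = 0.356, rho = 0.384, adjusted p = 0.00483) was 0.0113 after quantile normalization (adjusted p = 0.961), and that to B and plasma cells (r = 0.345, rho = 0.237, adjusted p = 0.00615) was 0.184 (adjusted p = 0.209). No relation was found to neutrophils (r = 0.199, rho = 0.157, 95% interval -0.0437 to 0.419, adjusted p = 0.138) or to general glandular epithelium (r = 0.0676, rho = -0.00355, interval -0.176 to 0.303, adjusted p = 0.63). General glandular epithelium and fibroblasts were not related either (r = -0.0162, rho = -0.0301, adjusted p = 0.896), but passed after quantile normalization with r = -0.335 (adjusted p = 0.0107).

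Neutrophil and acute inflammation genes rose with hypoxia and glycolysis (r = 0.662, rho = 0.646, permutation p = 1e-05; 0.676 without the 2 farthest libraries). Intestinal genes rose with bile acid, lipid and xenobiotic handling (r = 0.664, rho = 0.687, permutation p = 1e-05; 0.652), but not detectably with gastric mucous genes (r = 0.177, rho = 0.184, permutation p = 0.152, adjusted p = 0.192; 0.273 and passing without the 3 libraries with a gene above 100000 TPM) or WNT targets (r = 0.174, rho = 0.123, adjusted p = 0.193). Within the 64 libraries of the lower gastric gland part, gastric gland genes rose with gastric mucous genes (r = 0.541, rho = 0.476, permutation p = 1e-05; 0.444). Proliferation rose with the fibroblast score (r = 0.61, rho = 0.612; 0.611), with r = 0.399 after quantile normalization (adjusted p = 0.00197). Its relations to hypoxia (r = 0.422, rho = 0.213) and to glandular epithelium (r = 0.371, rho = 0.193) rested on 2 libraries, without which r was 0.185 and 0.11.

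Within the 41 libraries of the higher squamous part, squamous genes ran against the gastric mucous, general glandular and intestinal scores. They correlated with gastric mucous epithelium at r = -0.495 (rho = -0.509, permutation p = 0.00113, adjusted p = 0.00219), with general glandular epithelium at r = -0.476 (rho = -0.553, permutation p = 0.00156, adjusted p = 0.00283) and with intestinal epithelium at r = -0.423 (rho = -0.409, permutation p = 0.00554, adjusted p = 0.00803). Without the 2 farthest libraries these were -0.498, -0.473 and -0.351. The intestinal relation did not pass after quantile normalization (r = -0.302, adjusted p = 0.0936). Other genes also fell with the squamous score in this part. The 17 general glandular genes had a median slope of -0.241 on it, against -0.300 for genes of like level. Of these 17, 8 had a slope below that of genes of like level. A fall beyond that of other genes was thus not shown for glandular genes, and was not tested for gastric mucous and intestinal genes. In the 26 libraries of the lower part the correlations were -0.139, 0.101 and 0.154, with adjusted p of 0.554, 0.642 and 0.524; the difference between the parts was not tested.

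**Figure D3:**
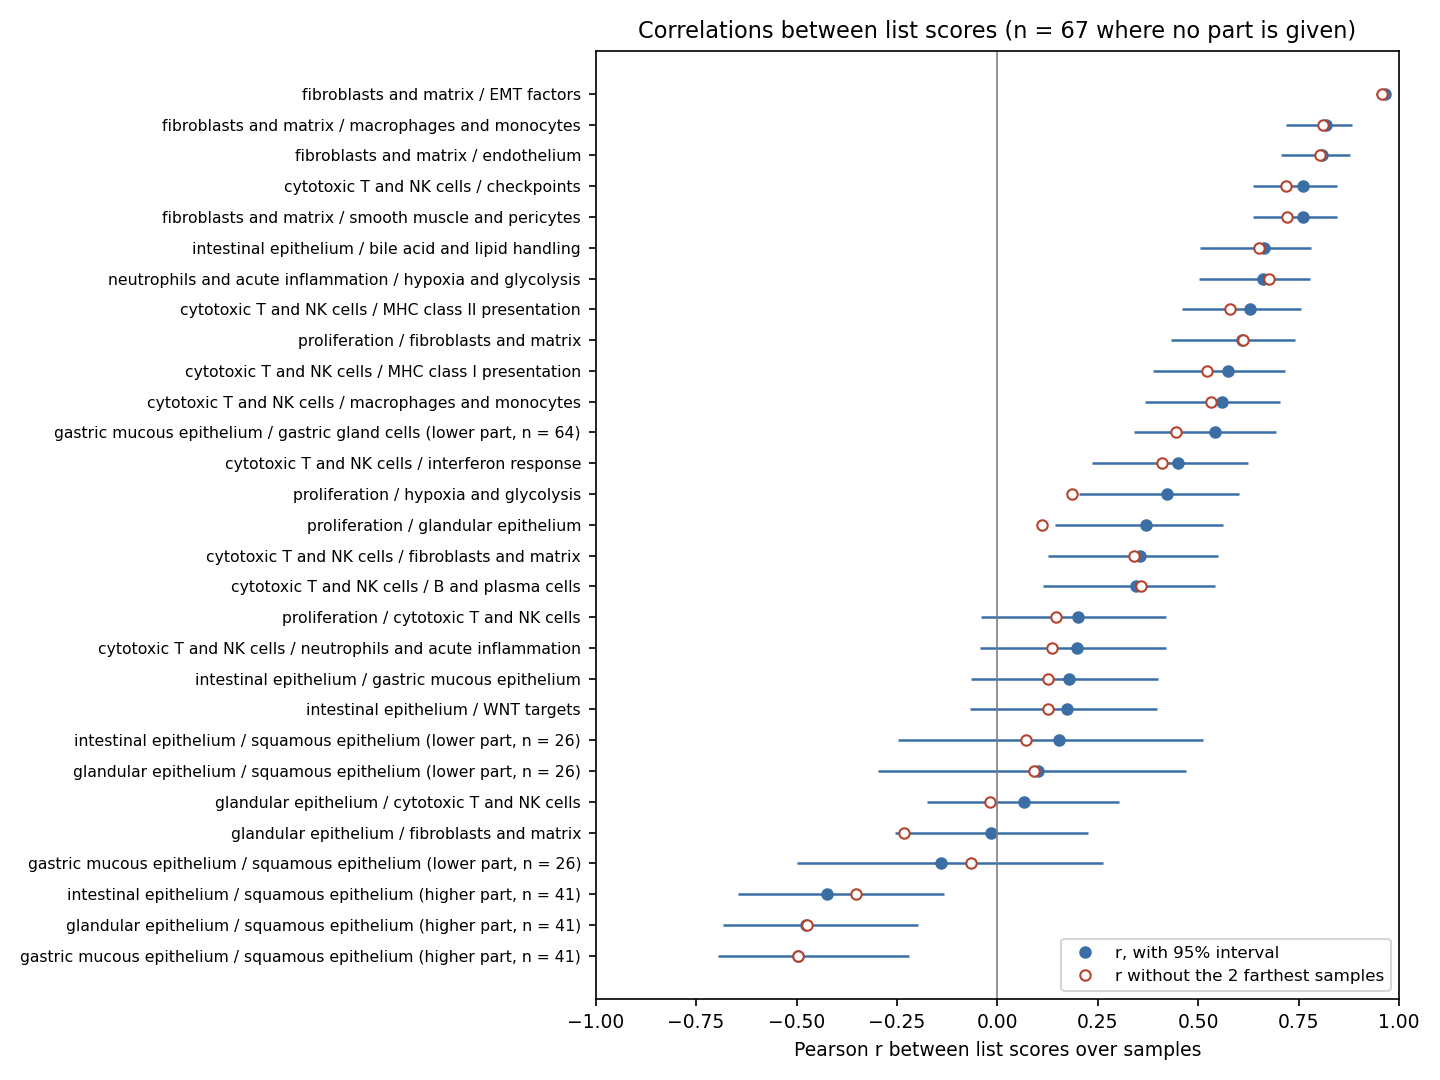
Pearson r between pairs of list scores over libraries (filled points, with 95% Fisher intervals) and r without the 2 libraries farthest from the median (open points); n is 67 unless a part is named. Fibroblast scores correlate with transition factors at r = 0.965, and squamous with general glandular scores at r = -0.476 in the higher squamous part. A fall of glandular genes beyond that of genes of like level was not shown there.

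The fourth question concerned 20 driver genes known from oesophageal adenocarcinoma, and whether their levels moved with those of genes next to them. Several drivers had a few libraries far above the rest. ERBB2 (chromosome 17, 39687914 to 39730426, hg38) exceeded its median by over 3 scaled median absolute deviations in 6 libraries, with a highest level of 4730 TPM, 41.5 times the median. CCNE1, the cyclin of S-phase entry (chromosome 19, 29811898 to 29824308), did so in 4 libraries and reached 567 TPM against 13.6. EGFR was far above its median in 4 libraries (highest 2080 TPM, median 50.5), MDM2 in 4 (460 TPM, median 41.4) and MET in 2 (1380 TPM, median 69.2). MYC, GATA4, GATA6, ERBB3, FGFR1 and KLF5 exceeded that limit in no library. At 5 scaled median absolute deviations the counts were 4 for ERBB2, 3 for CCNE1, 2 for EGFR, 2 for MDM2 and 0 for MET. GATA4, a transcription factor of foregut epithelium, was spread widely, from 0 to 324 TPM.

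CCNE1 fell into separate parts of 63 and 4 libraries, divided between 53.8 and 155 TPM. Libraries far above a driver's median were counted only and not compared with the rest.

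**Figure D4:**
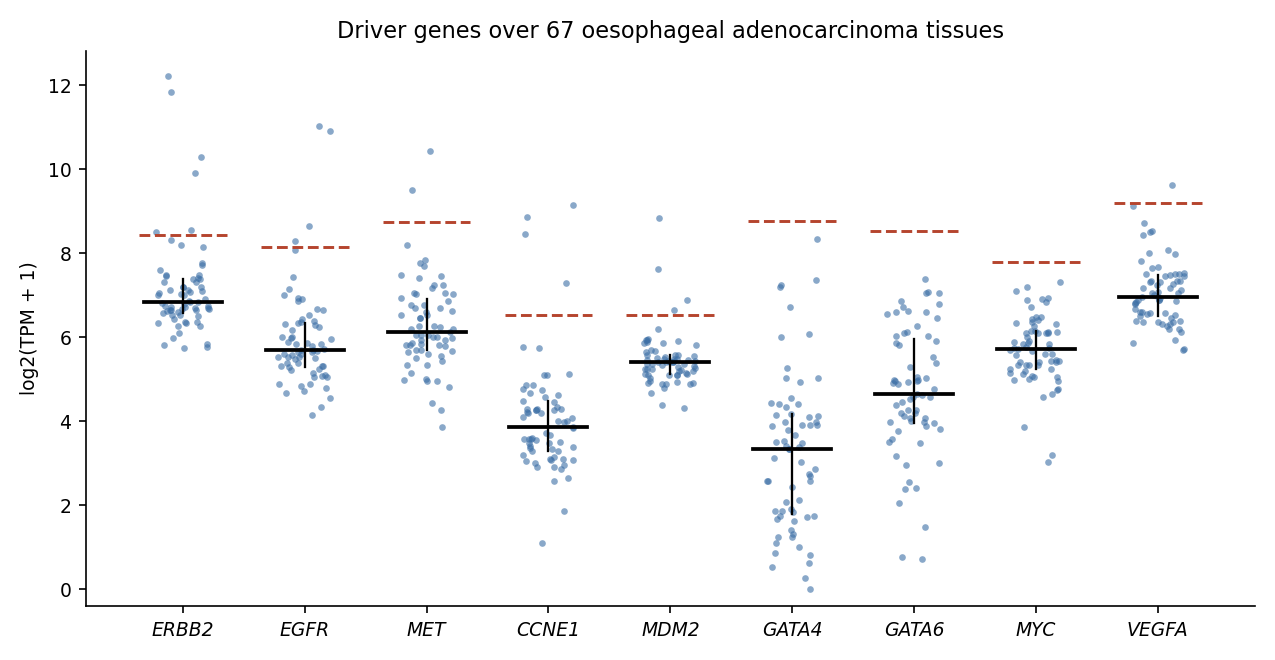
Levels of 9 driver genes in 67 libraries on the log2(TPM + 1) scale, each point being 1 library; solid bars are medians, vertical bars quartiles and dashed bars the median plus 3 scaled median absolute deviations. ERBB2 has 6 libraries above the dashed bar, and MYC, GATA4 and GATA6 have 0.

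Drivers rose with their chromosomal neighbours. Of 47 relations, 40 passed at an adjusted p under 0.05 (permutation tests, two-sided, Benjamini-Hochberg over the 47 relations), and in 21 r was above that of all 1000 random genes of like level on other chromosomes. EGFR correlated with SEC61G at r = 0.798 (rho = 0.393) and with LANCL2 at r = 0.778 (rho = 0.403), which were 0.557 and 0.567 without the 2 farthest libraries. MET correlated with CAPZA2 at r = 0.813 (rho = 0.699; 0.7), GATA4 with NEIL2 at r = 0.764 (rho = 0.66; 0.695) and PRKCI with PHC3 at r = 0.751 (rho = 0.629; 0.628), each with permutation p = 1e-05.

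Within the 63 libraries of the lower ERBB2 part, PGAP3 correlated with ERBB2 at r = 0.691 (rho = 0.721) and GRB7 at r = 0.637 (rho = 0.497). Within the 63 libraries of the lower CCNE1 part, POP4 and URI1 correlated with CCNE1 at r = 0.748 (rho = 0.688) and r = 0.743 (rho = 0.712). MCL1 differed from these, with r = 0.102 for ENSA (rho = -0.126) and -0.232 for GOLPH3L (rho = -0.223; adjusted p of 0.406 and 0.0678), and after quantile normalization the GOLPH3L relation passed as a negative one (r = -0.463, adjusted p = 0.000134). The relations of EGFR to VOPP1, MET to CAV1 and GATA4 to CTSB (r = 0.595, 0.411 and 0.388) did not pass without the 2 farthest libraries (r = 0.244, 0.212 and 0.253).

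The genes with the largest spread were squamous or gastric. The 20 genes with the largest SD of log2(TPM + 1) included GKN1 (SD 3.78, n = 67; 0 to 175000 TPM), PGC (3.74), LIPF (3.67), PGA3 (3.58) and TFF2 (3.57), all secreted by the gastric mucosa. The others included the squamous keratins KRT4 (3.68), KRT6A (3.56) and KRT13 (3.54), the cornified envelope genes CRNN (3.62), SPRR3 (3.55) and SPRR2A (3.51), the crosslinking enzyme TGM3 (3.56), the alarmin S100A7 (3.57) and the ammonium transporter RHCG (3.54). Over all genes past the filter 2458 had an SD above 1 and 273 above 2. With a pseudocount of 0.1, 7 of the 20 genes stayed among the 20. The genes with the highest means were MT-CO3 (26430 TPM), MT-CO1 (23490 TPM), S100A9 (16920 TPM), MT-CO2 (11380 TPM) and KRT13 (10240 TPM).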

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

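Alternatives for the parts of TP63 and ERBB2, the mitochondrial and squamous covariates and the libraries with a gene above 100000 TPM were added after seeing the data. The count of genes associated with CDX2 was 4910; it was 3224 by Spearman correlation, 2324 without the 2 samples farthest from the median, 401 with tissue composition covariates, 1264 after quantile normalization and 1395 with the mitochondrial share as a covariate. For MUC5AC, 2991 genes became 1989 with the mitochondrial share. For TP63, 10390 became 6618 with composition covariates, 6755 after quantile normalization and 1 within the lower part. For CD8A, 164 became 109 without the 2 farthest samples and 267 with composition covariates. For COL1A1, 11447 became 6519 after quantile normalization. For MKI67, 11013 became 2489 with composition covariates and 3670 after quantile normalization. For ERBB2, 53 became 107 with no filter, 8 by Spearman correlation, 82 without the 2 farthest samples, 475 with composition covariates and 10 within the lower part. The lower parts hold fewer samples and a narrower range of the anchor; for the others the cause was not tested. Of the 53 ERBB2 genes 4 were shared with the Spearman calls and 18 with those without the 2 farthest samples.

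The libraries counted far above the median summed to 41 over 20 drivers, and to 18 at 5 median absolute deviations. With a pseudocount of 0.1, 7 of the 20 most variable genes stayed. The count of list relations past the test was 20, and 16 to 20 over the alternatives; that of driver-neighbour relations was 40, and 36 to 41. Of 1307 slopes of named genes under alternatives, 1221 kept their call or the lack of one, 67 lost the call, 9 gained it and 10 turned with a call before or after; a change of sign between slopes without a call is not counted. Those that turned were, within the lower part of TP63, PDXP (0.40), PDE4DIP (0.21), KLF9 (0.029), PDIA5 (0.051), COL1A1 (1.26) and MKI67 (1.28), none of them called there; COL1A1 with TP63 given composition covariates (0.019), of which the fibroblast score contains COL1A1 and so shrinks its slope by construction; CDH17 with TP63 within the higher part (-0.60); and EIF1 with ERBB2, by Spearman correlation (-0.027) and within the lower part (-0.026). The correlation of MCL1 and ENSA turned to -0.359 without the libraries with a gene above 100000 TPM. Levels of 7 of 33 lists, all of low genes, moved by over 1 SD with a pseudocount of 0.1. No paired analysis was possible because the labels hold 1 group.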

Other observations

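The tests of the glandular level, of abundant genes, of the 3 libraries with a gene above 100000 TPM, of overlapping genes and of permuted anchors were chosen after the results were seen. Those of suprabasal genes, distance and cell type scores were not, but the parts of libraries they used followed a rule set after seeing the data. Cancer-testis antigens, genes of the germ line that tumours can express, were on in a subset of tissues. MAGEA3 was at 1 TPM or more in 29 of 67 libraries and reached 264 TPM, with a median of 0.574 TPM. MAGEA6 was at that level in 25 libraries and MAGEA12 in 18. The score of the list placed 23 libraries in a higher part and 44 in a lower. PRAME was at 1 TPM or more in 35 libraries.

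Most genes of liver and neuroendocrine cells were low, but the liver gene SERPINA1 had a median of 98 TPM. ALB, the main liver product, was at 1 TPM or more in 9 libraries, and ADIPOQ, an adipocyte hormone, in none, with a highest value of 0.0977 TPM. The neuroendocrine secretory granule gene CHGA had a median of 1.37 TPM and reached 1090 TPM. The haemoglobin gene HBB had a median of 49.3 TPM (4.17 to 3640). The muscle gene TTN had a median of 3.1 TPM. The WNT target AXIN2 had a median of 10.6 TPM (0.928 to 133), and the heat shock gene HSPA1A of 260 TPM.

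Squamous genes were high in most of these adenocarcinoma libraries. Squamous genes added to an unchanged glandular level would lower glandular genes only as far as other genes, through the fixed sum of the TPM. Within the 41 libraries of the higher part, the median difference in slope on the squamous score between 17 glandular genes and genes of like level was 0.109 (95% bootstrap interval -0.354 to 0.409), so this stays open. Squamous mucosa present in the tissue piece is a candidate explanation, since mucosa brings its basal and upper layers together. In those 41 libraries 6 suprabasal genes followed 4 basal genes with a median log2 slope of 1.22 (95% bootstrap interval 0.98 to 1.484), where an interval below 0.5 would have argued against it. All of these genes belong to the list whose score defined the part, and that list moved as a block with TP63. The slope therefore adds little support for included mucosa. Over all 67 libraries, all 20 squamous genes had a median of 1 TPM or more, KRT6A of 3570 TPM and KRT13 of 3160 TPM. Squamous tumour cells with both layers would give the same slope, and no biological explanation was tested, as the labels hold 1 group.

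Most genes moved in the same direction with COL1A1 and MKI67, and in the opposite direction with TP63. Without the 3 libraries with a gene above 100000 TPM, 87.8% of MKI67 calls were still higher, which argues against these libraries as the whole source. For a few very abundant genes taking a large share of the TPM, each library was rescaled by the share outside its 20 highest genes. The median slope of all genes then kept 56.7% of its size as a median over the 3 anchors (95% bootstrap interval 38.8% to 72.3%). It kept 47.1% for MKI67 (21% to 72.9%), 56.7% for COL1A1 (38.8% to 69.8%) and 84.6% for TP63 (69.1% to 127%). The interval spans the limit set for this test, so how much very abundant genes contribute stays open. Abundant genes below the 20 highest also draw on the fixed sum and were left in.

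Drivers and their chromosomal neighbours were high together. Reads shared between overlapping genes are argued against as the whole source, since in 17 of 41 relations with a neighbour that does not overlap its driver r exceeded that of all random genes. A mixture of squamous, glandular, fibroblast and cytotoxic cells alone is argued against as well. All 40 relations past the test kept an adjusted p under 0.05 and r above 0 with these 4 scores regressed out. Other cell types were not regressed out, and this test was against an r of 0, not against random genes. Before that step, r was above that of 95% of random genes in 34 of 47 relations. Gain of the chromosomal segment, a hypothesis, may contribute: the median r of genes within 0.5 Mb exceeded that of genes 2 to 10 Mb away by 0.248 over 15 drivers (95% bootstrap interval 0.169 to 0.288), and did so for 12 of them, with drivers in separate parts taken in the lower part, a restriction added after a first result. Regulation shared by adjacent genes would give the same decline with distance and was not tested.

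Permuting the anchor values over the libraries gave as many genes in 0 of 100 draws for CDX2 (highest 1172), MUC5AC (583), TP63 (0), COL1A1 (1) and MKI67 (371). Chance pairing thus gave no total count as large in that number of draws. The test covers the total count and not single genes, since permuted CDX2 values still called up to 1172 genes. For CD8A and ERBB2 1 of 100 draws gave as many. The highest counts, 649 and 3834, were far above the real counts of 164 and 53, and the cause was not tested.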
